A study of Mus musculus with 16 samples.

How the data were processed

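The deposited table holds log2 values of Cy5 spot intensities that the authors had centred on the mean of each array. The sources used here do not spell out the centring, which was read from the values. Raised back to intensities, 100% of spots under 200 were whole numbers within 0.005 on every array, and 15 of 16 array means lay within 0.001 of 0. MSC replicate 3 had a mean of 0.300 instead. Each array carried a single repeated value at 3.38% to 13.8% of probes, taken here as a fill for spots without a usable signal. On some arrays this fill value lay above the lowest other value (-5.83 against -6.43 on MSC replicate 1). Per the labels, total RNA was amplified to cDNA with a WT-Ovation Pico kit and labelled with a Cy5 ester, and the series text says that only the Cy5 channel of a 2-colour array was used. Scanner settings, background correction and the rule behind the fill value are not given in the sources used here. No count of cells, sort purity or animal number per sample is given there either.

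All 26423 probes of the 16 arrays entered. Array medians spread over 1.45 log2 units (from -1.02 to 0.43) and array SDs ranged from 2.90 to 4.05, so by a rule fixed beforehand, which allowed medians to differ by 0.5, the values were quantile normalised over all probes (normalizeQuantiles in limma). A mouse annotation table of assembly GRCm38 gave names only. Of the probes, 20377 had a symbol and 6046 had none; 18213 matched a current symbol, 2126 a synonym, and 38 were ambiguous and left out with the unnamed ones. This gave 17710 genes, 15437 with 1 probe and 2273 with several, for which the probe with the highest mean was used.

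A linear model with 6 group means was fitted to the 16 arrays with limma 3.58.1 in R 4.3.3, with default empirical Bayes moderation (prior degrees of freedom 3.81, prior variance 0.911, residual degrees of freedom 10). Each of 11 comparisons was a contrast, given as the log2 difference of the first minus the second group with its SE, and p-values were adjusted by Benjamini-Hochberg over the 17710 genes of the comparison. A gene was called at an adjusted p under 0.05. The interaction of organ and cell class was a contrast of the same model. The contrast for cardiac progenitors gives equal weight to the 3 cardiac populations.

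The 26 gene lists were written from general knowledge before the data were examined. They were tested with camera in limma with its preset correlation of 0.01 and again with a correlation estimated from the data, adjusting over the 26 lists of a comparison, and with fry in limma. Counts "adjusted over the list alone" use Benjamini-Hochberg over the members of a list. Missing members were not used here, and the sarcomere list has 11 of 24 and the Notch list 11 of 18 members measured. Distance to cardiomyocytes was the root mean square log2 difference over all genes from the mean of the cardiomyocyte arrays, tested by permuting group labels 100000 times and, for pairs of groups, by all exact permutations.

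Named genes were picked by a fixed rule: the sort markers, the 5 highest and 5 lowest called genes whose groups did not overlap, and up to 4 called members, the largest by log2 difference, of each of the 6 top lists of a comparison. From the other lists the 2 members with the largest absolute log2 difference were eligible. Unless stated otherwise, every array of a side lay beyond every array of the other for genes named by this rule with an adjusted p under 0.05. Between heart Sca1 cells and cardiomyocytes, where the rule gave almost no gene, list members were chosen after their values were seen. Genes at the fill value on all arrays of a side were not named, and large differences with a side near the fill value are uncertain in size. The brightest spot of every array stood at 65436 to 65471, close to the limit of a 16-bit scanner, and 1 to 37 spots per array lay within 5% of it. For named genes among them the report gives the number of such arrays, and their differences are uncertain in size as well. This check was added after the results were seen.

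Alternatives were alignment of medians in place of quantile normalisation, the deposited values unchanged, removal of the 30% of genes with the lowest mean, raising of low values to the 30th percentile, the mean over the probes of a gene, moderation with trend and robust options, a block for replicate number, array weights per group, a distance of 1 minus the Pearson correlation, fits of only the groups compared and fits that left out an array at a time.

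The procedure was tried on simulated arrays with the group sizes of the real ones and the spread of each gene, but with genes independent of each other, in 3 runs with 17710 genes and 200 changed genes each. In a comparison of 3 with 3 arrays it recovered 1.33%, 2%, 44% and 82.7% of genes with true log2 differences of 1, 2, 4 and 6. For 3 arrays against 2 cardiomyocyte arrays it recovered 0%, 1.33%, 37.3% and 73.3%. Against the 2 side population arrays it recovered 0%, 0%, 36% and 73.3%. Of 52530 unchanged genes, 11, 7 and 6 were called. A shifted list was called in 3 of 3 runs and 0 other lists were, on simulated values that were not quantile normalised. Since the simulated genes were independent, these runs cannot show how often lists of correlated genes are called falsely. In these simulations differences of 1 and 2 log2 units were therefore mostly missed, and no size between 2 and 4 was tried. With only 200 changed genes the adjustment is stricter than where many genes change. The shares recovered need not hold for the real comparisons, where smaller differences could pass. Each gene was also drawn with the same spread in all groups, while the real heart c-kit and side population arrays varied more than the others. In comparisons with these groups recovery may be lower and false calls more frequent than simulated. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.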

Results

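Genome-wide expression was read on 16 mouse arrays, in 5 progenitor or stem cell populations and in cardiomyocytes from C57BL/6 mice. Of the heart, 3 arrays held cells sorted for the receptor tyrosine kinase c-kit (heart c-kit cells), 3 held cells sorted for stem cell antigen 1 that lacked the leukocyte antigen CD45 and the endothelial antigen CD31 (heart Sca1 cells), and 2 held side population cells, which are picked by their export of a Hoechst dye. Of the bone marrow, 3 arrays held cells sorted for c-kit (marrow c-kit cells) and 3 held mesenchymal stem cells grown for 5 passages (marrow MSC). The cardiomyocytes, collected by slow centrifugation, were on 2 arrays. The median spot intensity ranged from 15 to 200 between arrays. It was 15 and 22 on the side population arrays and 18 on heart c-kit replicate 2, so many genes lay near the floor there. The labels do not say whether replicates came from separate animals or cultures, so every p-value measures the spread between these arrays, which may be technical in part. The small number of arrays limits the precision of every comparison.

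Replicates resembled each other most in the marrow groups. Pearson correlations across genes, which are not independent replicates, were 0.925 to 0.932 between the marrow c-kit arrays and 0.935 to 0.942 between the MSC arrays. They were 0.910 to 0.917 for heart Sca1 cells, 0.894 for the pair of cardiomyocyte arrays, 0.791 to 0.805 for heart c-kit cells and 0.748 for the side population pair. The model shares 1 estimate of the spread of each gene over all groups. Adjusted p-values and counts that involve heart c-kit or side population cells may therefore be too favourable, and those for the tighter groups too strict.

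The markers used for sorting were read first. Kit, which encodes c-kit, was highest in marrow c-kit cells (log2 level 5.5 ± 0.32, SD, n = 3) and next in heart c-kit cells (3.67 ± 1.46, SD, n = 3). Kit was 1.26 ± 1.27 in cardiomyocytes (SD, n = 2), -0.24 ± 0.23 in side population cells (SD, n = 2), -1.57 ± 1.74 in heart Sca1 cells (SD, n = 3) and -1.61 ± 0.19 in MSC (SD, n = 3). Heart c-kit cells exceeded heart Sca1 cells in Kit by 5.24 ± 0.87 (SE; limma adjusted p = 0.00169). Ptprc, which encodes CD45, reached 7.51 ± 1.09 in marrow c-kit cells and 7.05 ± 0.43 in MSC, against 4.26 ± 0.06 in cardiomyocytes, 4.01 ± 1.14 in heart c-kit cells, 0.82 ± 1.95 in heart Sca1 cells and -1.31 ± 1.36 in side population cells. The probes of Ptprc disagree: between heart c-kit and heart Sca1 cells they gave log2 differences of 3.20 and -1.44. Pecam1, which encodes CD31, was 6.02 ± 1.5 in heart c-kit cells, 5.83 ± 1.34 in cardiomyocytes, 4.78 ± 0.77 in side population cells, 3.45 ± 1.90 in heart Sca1 cells, 2.85 ± 1.87 in marrow c-kit cells and -3.04 ± 0.86 in MSC. Abcg2, a dye exporter of side population cells, had its lowest mean in that very population, at 2.50 ± 2.70 (0.59 and 4.41 on its arrays). It was 4.89 ± 0.38 in heart c-kit cells, 4.15 ± 0.76 in cardiomyocytes, 3.82 ± 0.19 in heart Sca1 cells, 3.33 ± 0.27 in MSC and 2.76 ± 0.57 in marrow c-kit cells. Ly6a, the gene of Sca1, was not analysed here.

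**Figure D1:**
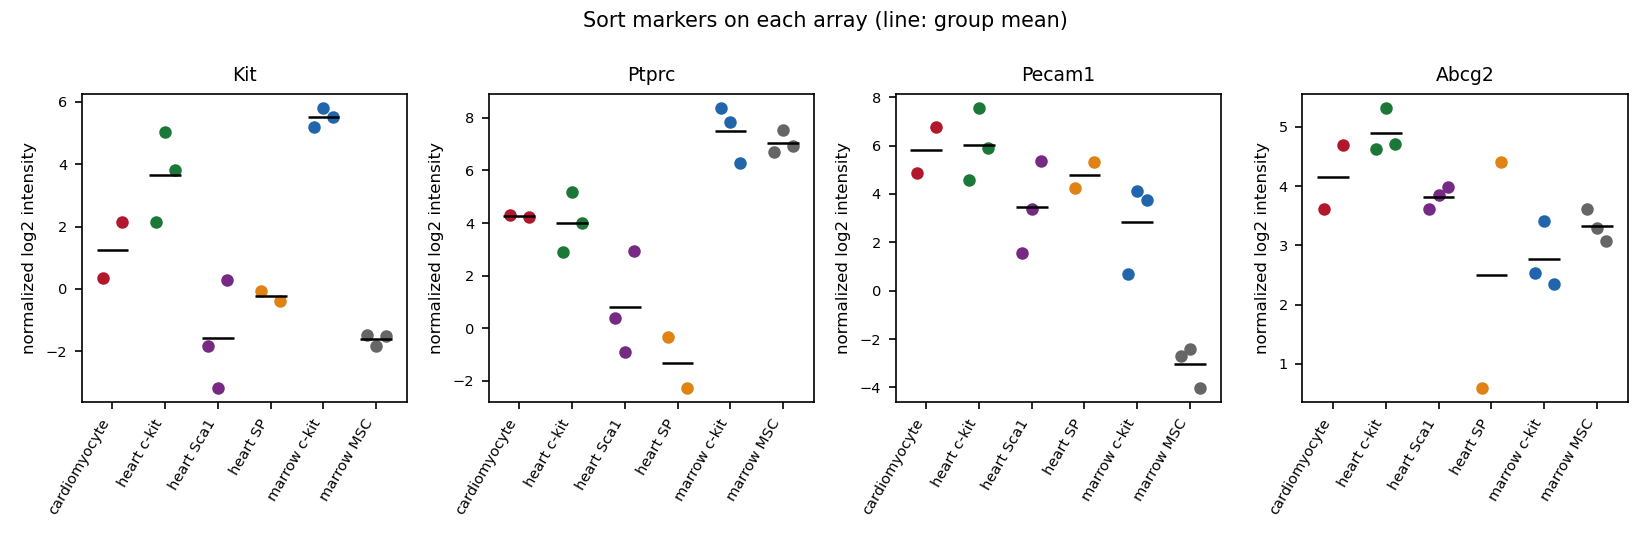
Normalised log2 intensity (y axis) of Kit, Ptprc, Pecam1 and Abcg2 in the 6 groups (x axis); each point is an array and each line a group mean. Kit stood at 5.5 in marrow c-kit cells and 3.67 in heart c-kit cells, and Ptprc at 7.51 in marrow c-kit cells and 7.05 in MSC.

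The first question was which population lay nearest to cardiomyocytes over all 17710 genes. Heart Sca1 cells did, with a root mean square log2 difference from the cardiomyocyte mean of 1.68 ± 0.13 (SD, n = 3). MSC followed at 2.11 ± 0.10 (n = 3), heart c-kit cells at 2.16 ± 0.23 (n = 3), marrow c-kit cells at 2.37 ± 0.05 (n = 3) and side population cells at 2.42 ± 0.04 (n = 2). Each cardiomyocyte array lay 0.835 from the mean of the pair. Between single arrays the root mean square difference was 2.62 for side population cells, 2.28 to 2.37 for heart c-kit cells and 1.67 for cardiomyocytes. For side population and heart c-kit cells this exceeds the mean distance from cardiomyocytes. That distance is taken to a mean of 2 arrays, however, which carries less noise than a single array. Arrays of the same group lay 1.24 to 1.55 apart among MSC, marrow c-kit and heart Sca1 cells. The distance of an array includes its own noise, so unequal noise may account for part of the ranking. The 5 populations differed in this distance (permutation test of the group labels with 100000 resamples, on the variance between group means, p = 0.00400), and the farthest exceeded the nearest group mean by 0.738. That call was lost with medians aligned only, where the gap was 0.962 with a permutation p of 0.0549, and marrow c-kit cells came second at 2.23 behind heart Sca1 cells at 1.90. With low values raised to the 30th percentile heart c-kit cells came second, at 1.75 behind 1.37. Marrow c-kit cells were then the farthest at 2.02, and they also were at 2.49 without the lowest 30% of genes. Without cardiomyocyte replicate 2, the array that heart Sca1 replicate 3 resembled most (r = 0.933), heart Sca1 cells lay at 2.13 and the next group, heart c-kit cells, at 2.23, and without heart Sca1 replicate 3 the group lay at 1.76. Without cardiomyocyte replicate 2 the gap between farthest and nearest was 0.427 with a permutation p of 0.114, and without side population replicate 1 the gap was 0.708 with p = 0.0665. All 3 heart Sca1 arrays lay nearer than every array of the other groups. No pair of groups could reach significance, since the smallest exact permutation p that 3 against 3 arrays allow is 0.1. That was the value for heart Sca1 cells against each of the other 4 groups (0.167 after Benjamini-Hochberg adjustment over 10 pairs).

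**Figure D2:**
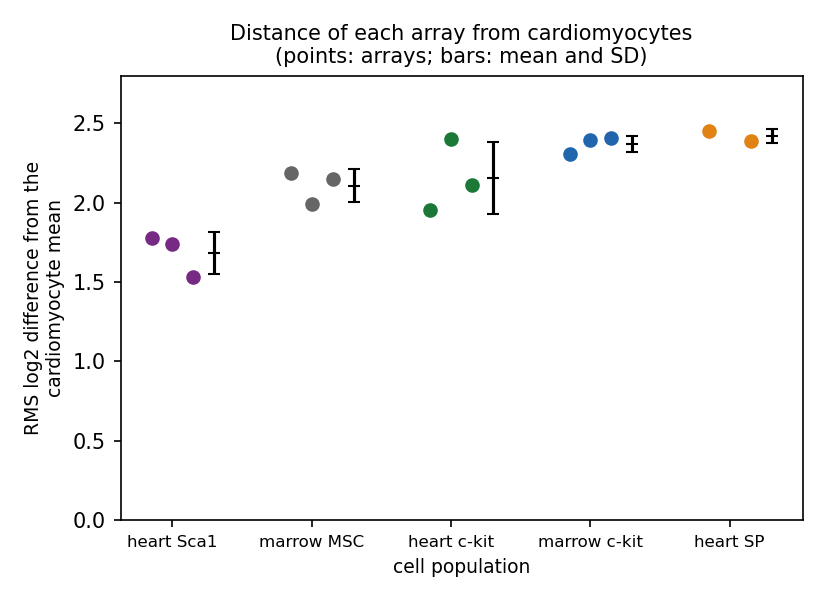
Root mean square log2 difference of each array from the cardiomyocyte mean (y axis) by population (x axis); points are arrays, bars the group mean and SD. The heart Sca1 arrays lie at 1.53, 1.74 and 1.78, below the other arrays, which start at 1.95.

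Cardiac progenitors as a whole were set against cardiomyocytes, the comparison that the series design names. The mean of the 3 cardiac populations fell below cardiomyocytes in genes of heart muscle and of endothelium. All 11 measured sarcomere genes had negative log2 differences (median -2.95; limma camera adjusted p = 5.38e-16), and 6 of them passed over all genes (9 when adjusted over the list alone). Tnni3 and Tnnc1, the inhibitory and calcium-binding troponins, fell by 4.96 and 4.37 on the log2 scale. Sln, which encodes the calcium pump regulator sarcolipin, fell by 7.51 with 1 of 8 progenitor arrays at the fill value, and Gja5, a gap junction protein of the atria and arteries, fell by 4.87.

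In total, with gene lists fixed before the data were examined, limma called 120 of 17710 genes at an adjusted p under 0.05, with 24 higher and 96 lower in cardiac progenitors, and 2097 genes had an unadjusted p under 0.05. The calcium handling and ion channel list was lower (median -2.32, camera adjusted p = 6.03e-11; 3 of 20 members passed, 10 when adjusted over the list alone). Endothelial genes were lower as a list (median -3.67, camera adjusted p = 1.33e-18), with all 23 members below 0. Only Vwf (-7.35 ± 1.12, SE, limma adjusted p = 0.0220; at the fill value on 1 progenitor array) and Ptprb (-4.25 ± 0.83, adjusted p = 0.0377) passed over all genes, and 16 passed when adjusted over the list alone. Macrophage and leukocyte genes had a median of -3.04 (camera adjusted p = 3.24e-12, but adjusted p = 0.0542 with an estimated correlation). Of these, Laptm5, a lysosomal protein of blood cells, was -3.29 ± 0.69, although progenitor and cardiomyocyte arrays overlapped, and 13 of 20 members passed when adjusted over the list alone. The cardiomyocyte arrays themselves carried these markers: their mean endothelial level was 6.35 and 6.52 and their mean macrophage level 2.76 and 3.62. The smooth muscle list (median -1.65, camera adjusted p = 7.48e-07) included Acta2, smooth muscle actin, at -4.62 ± 0.85, and the Notch list (11 of 18 genes measured) had a median of -1.65 (camera adjusted p = 2.29e-05). The cardiac stress list, with natriuretic peptides, had a median of -0.72 (camera adjusted p = 0.00832). Immediate early genes had a median of -0.99 (camera adjusted p = 7.04e-06) that turned to 1.23 with medians aligned only and to 0.50 with the deposited values (adjusted p = 0.306 and 0.364). ABC transporters had a median of -0.75 (camera adjusted p = 0.0319, but adjusted p = 0.132 with an estimated correlation), and it turned to 0.84 and 0.11 under the same scalings.

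Of single genes higher in cardiac progenitors, Timp1, an inhibitor of matrix metalloproteinases, differed by 5.21 ± 0.77 (adjusted p = 0.0201), Lif, a cytokine of the interleukin 6 family, 4.45 ± 0.88 (adjusted p = 0.0377) and Ereg, a ligand of the EGF receptor, 3.80 ± 0.66 (adjusted p = 0.0294). Akr1b8, an aldo-keto reductase, was 4.27 ± 0.83 higher (limma adjusted p = 0.0371). The count changed with nearly every choice in the analysis. limma called 1 gene without cardiomyocyte replicate 1, 2 without replicate 2, and 0 when only the arrays compared were fitted. It was 0 with medians aligned only and 2, both lower, with the deposited values, and it also moved to 52, 46 and 238 without heart Sca1 replicates 1, 2 and 3, to 183 without heart c-kit replicate 1 and to 219 and 240 without side population replicates 1 and 2. A block for replicate number gave 38 genes, array weights per group 4, removal of the lowest 30% of genes 228, trend and robust moderation 196 and raising of low values 505.

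Heart c-kit cells differed from cardiomyocytes most clearly in immediate early, matrix and muscle genes, all lower. Fosb and Fos, early transcription factors of the AP-1 complex, were -6.82 ± 0.76 and -5.92 ± 0.86 (SE; limma adjusted p = 0.000311 and 0.00194), with Fosb near the scanner ceiling on 1 of 2 cardiomyocyte arrays. Acta2 was -8.42 ± 0.98 (-4.89 by its other probe) and Sln -7.60 ± 0.90. Akr1b8 was 6.52 ± 0.95 higher, at 7.66 ± 0.36 (SD, n = 3) against 1.14 ± 0.93 (SD, n = 2), and Spp1, which encodes osteopontin, was 6.18 ± 0.73 higher.

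Over all genes, limma called 634, of which 176 were higher and 458 lower in heart c-kit cells (72.2% lower; 2845 genes at an unadjusted p under 0.05). Of 20 immediate early genes, 8 fell and 12 did not pass (13 lower when adjusted over the list alone; median -2.36, camera adjusted p = 1.27e-11). Of 26 fibroblast and matrix genes, 9 fell and 1 rose (median -2.82, camera adjusted p = 1.91e-11). They included Col1a2, a chain of type I collagen (-4.48 ± 1.07), and Pdgfrb, a receptor of mesenchymal cells (-4.39 ± 0.78). Of 11 sarcomere genes, 5 fell (9 when adjusted over the list alone; median -3.46, camera adjusted p = 3.72e-10), with Tcap, a Z-disc protein, at -6.59 ± 1.23 and Actn2, sarcomeric actinin, at -4.68 ± 0.72. The calcium handling list fell (median -2.55, camera adjusted p = 6.21e-08; 6 members), including the sarcoplasmic calcium pump gene Atp2a2 (-5.10 ± 0.93; its other probes gave smaller differences, down to -1.84). The smooth muscle list fell (median -2.15, camera adjusted p = 4.22e-07; 3 members), with Rgs5, a pericyte gene, at -4.03 ± 0.74 and Des at -3.82 ± 0.64. Cardiac transcription factors had a median of -1.10 (camera adjusted p = 0.00237). The endothelial list had a median of -1.03 that turned to 0.89 with medians aligned only and to 0.19 with the deposited values (camera adjusted p = 0.000812, but adjusted p = 0.281 with an estimated correlation). Ramp2, an adrenomedullin coreceptor of endothelium, fell by 3.85 on the log2 scale and Vwf by 6.93. Of 14 mast cell genes, 2 rose and 1 fell (3 and 1 when adjusted over the list alone; camera adjusted p = 0.0537).

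A further 7 lists were called lower by camera with the preset correlation only. Macrophage genes (median -0.76) and epicardial genes (median -1.12) had adjusted p = 0.430 and 0.237 with an estimated correlation. The other 5 medians turned positive with medians aligned only: mesenchymal stem cell markers from -1.28 to 0.35, fatty acid oxidation from -0.54 to 0.54, growth factors from -0.42 to 0.57, Wnt genes from -0.80 to 0.27 and TGF-beta genes from -0.61 to 0.78 (0.07 with the deposited values). The median of all genes rose to 0.83 with medians aligned only, and these 5 lists stayed below it, TGF-beta genes only just. Their adjusted p was 0.154, 0.0652, 0.144, 0.0922 and 0.243 with an estimated correlation. With medians aligned only, 148 genes were called (60.8% lower), 223 with the deposited values, 242 with array weights and 1115 with low values raised. Without cardiomyocyte replicate 1 or 2 the count was 265 or 180, and 3 when only the arrays compared were fitted.

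No single gene passed between heart Sca1 cells and cardiomyocytes, the nearest pair. In this comparison limma called 0 genes over all 17710, while 2067 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0523, for S100a9 (log2 difference -6.18 ± 0.87, SE). Gene lists did differ: endothelial, sarcomere and cardiac stress genes were lower and fibroblast matrix genes higher.

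In the endothelial list the median log2 difference was -3.91 (camera adjusted p = 1.86e-16), and 18 of 23 members were lower when adjusted over the list alone. In the sarcomere list it was -3.08 (camera adjusted p = 7.73e-11; 9 of 11 members). Examples, chosen after their values were seen because no member passed over all genes, are Tnnc1 at -4.39 ± 0.90 (limma adjusted p = 0.0935) and Sox18, an endothelial transcription factor, at -5.73 ± 1.09 (adjusted p = 0.0924). Fibroblast and matrix genes had positive differences in 25 of 26 cases (median 1.11, camera adjusted p = 2.84e-08; 8 when adjusted over the list alone). Col5a1 was 3.71 ± 0.80 higher and Col3a1, the chain of type III collagen, 3.49 ± 0.76 higher, with adjusted p of 0.118 and 0.124. The calcium handling list had a median of -2.27 (camera adjusted p = 4.89e-08; 6 of 20 members when adjusted over the list alone), with Sln at -5.60 ± 0.90 (adjusted p = 0.0826). The cardiac stress list had a median of -2.11 (camera adjusted p = 1.98e-05; 5 of 9 members when adjusted over the list alone), with Nppa, the atrial natriuretic peptide gene, at -5.74 ± 1.19 (adjusted p = 0.0965). The Notch list (median -1.76), the smooth muscle list (median -1.47) and the cell cycle list (median -0.72) were also lower, with camera adjusted p of 0.000297, 0.000313 and 0.00405. The smooth muscle call was lost with medians aligned only (adjusted p = 0.0788) and with the deposited values (adjusted p = 0.0759). Macrophage and leukocyte genes had a median of -2.77 (camera adjusted p = 2.39e-10, but adjusted p = 0.0726 with an estimated correlation).

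Heart Sca1 replicate 3 stood apart in endothelial and macrophage genes. Its mean endothelial level was 5.14 against 1.56 and 2.15 on the other arrays of the group, and its mean macrophage level was 2.66 against -0.82 and -0.73, while Tnnt2, cardiac troponin T, was 4.34 against 3.98 and 4.77. Without that array limma called 164 genes (86.6% lower), without cardiomyocyte replicate 2 it called 11 and without heart Sca1 replicate 2 it called 1. It called 2 with the mean over the probes of a gene and 325 when values under the 30th percentile were raised to it.

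Side population cells had lower muscle genes than cardiomyocytes. Tnni3 was -8.0 ± 0.66 (SE; limma adjusted p = 4.05e-05), at -0.11 ± 0.34 (SD, n = 2) against 7.89 ± 0.30 (SD, n = 2). Cdh5, the cadherin of endothelial junctions, was -8.80 ± 1.71 and Laptm5 was -8.42 ± 0.86. Timp1 was 6.69 ± 0.98 higher (adjusted p = 0.00199).

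Here, limma called 916 genes, 334 higher and 582 lower in side population cells (63.5% lower), and 3752 had an unadjusted p under 0.05. Of 23 endothelial genes, 15 fell (19 when adjusted over the list alone; median -5.37, camera adjusted p = 1.83e-14, but adjusted p = 0.0746 with an estimated correlation). Robo4, an endothelial guidance receptor, was -8.17 ± 1.74 and Sox17, an arterial transcription factor, -7.53 ± 1.85. Of 20 macrophage and leukocyte genes, 9 fell (median -5.48, camera adjusted p = 3.47e-10, but adjusted p = 0.116 with an estimated correlation). Of 11 sarcomere genes, 6 fell (8 when adjusted over the list alone; median -3.18, camera adjusted p = 1.30e-09), with Tnnc1 at -5.18 ± 0.99. The calcium handling list fell (median -3.25, camera adjusted p = 5.26e-05; 4 members), with Gja5 at -5.32 ± 1.25 and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at -4.30 ± 1.09, and so did the Notch list (median -2.06, camera adjusted p = 0.000120). Of 26 matrix genes, 3 rose, namely Timp1, Col5a2 (4.05 ± 1.05) and Col3a1 (3.20 ± 0.83), and the list median was 1.56 (camera adjusted p = 0.000891, but adjusted p = 0.116 with an estimated correlation). The smooth muscle list had a median of -1.37 (camera adjusted p = 0.0172, but adjusted p = 0.116 with an estimated correlation). That median turned to 1.19 with medians aligned only, where the median of all genes was 1.34. Csf2, the gene of the cytokine GM-CSF, was 9.84 ± 1.37 higher, with 1 of 2 cardiomyocyte arrays at the fill value, and 5 of 24 chemokine and cytokine genes rose. Sez6l was 7.11 ± 1.11 higher and Arnt2, a transcription factor partner of HIF-like proteins, 6.94 ± 1.53 higher. Actc1, cardiac actin, was -12.09 ± 1.74, with 1 of 2 side population arrays at the fill value.

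The split between higher and lower genes in this comparison depended on scaling. With medians aligned only, 2619 genes were called, 8.82% of them lower. Without cardiomyocyte replicate 1 or 2 limma called 260 or 298 genes, and 0 when only the arrays compared were fitted. Array weights gave 128 and raising of low values 1486.

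Marrow c-kit cells differed from cardiomyocytes in granulocyte and proliferation genes, which were higher, and in matrix, endothelial, early response and muscle genes, which were lower. Mpo, the myeloperoxidase of granulocyte precursors, was 11.25 ± 0.69 higher (SE; limma adjusted p = 3.52e-07), at 9.56 ± 0.04 (SD, n = 3) against -1.69 ± 0.42 (SD, n = 2), but 2 of 3 marrow spots lay near the scanner ceiling, so the size is uncertain. Kit was 4.24 ± 0.98 higher (adjusted p = 0.0104). Cxcl1, a neutrophil chemokine, was -12.69 ± 0.77, and Sparc, a matrix glycoprotein, -11.85 ± 1.31.

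Here limma called 2200 genes, 884 higher and 1316 lower (59.8% lower), and 4135 had an unadjusted p under 0.05. Of 18 granulocyte and monocyte genes, 12 rose (14 when adjusted over the list alone; median 6.45, camera adjusted p = 2.36e-14). They included the granule proteases Ctsg (12.52 ± 1.02) and Elane (11.45 ± 0.94) and the membrane protein gene Ms4a3 (11.19 ± 1.2). Of 26 cell cycle genes, 16 rose (23 when adjusted over the list alone; median 4.38, camera adjusted p = 1.07e-12), among them the mitotic checkpoint kinase genes Bub1 (7.02 ± 0.99) and Bub1b (5.44 ± 0.93), the cyclin gene Ccna2 (6.46 ± 1.37) and Mcm2 of the replicative helicase (5.32 ± 1.2). Mast cell genes rose as a list (median 1.82, camera adjusted p = 0.00320; 4 of 14 members). Blood stem and progenitor genes had a median of 1.58, with 7 members higher and 2 lower (camera adjusted p = 0.0263, but adjusted p = 0.225 with an estimated correlation), and erythroid genes one of 0.77 (camera adjusted p = 0.0296, but adjusted p = 0.144 with an estimated correlation). Of 26 matrix genes, 22 fell (median -5.32, camera adjusted p = 1.15e-24), with the proteoglycan gene Dcn at -10.24 ± 0.86. Of 20 immediate early and heat shock genes, 18 fell (median -5.21, camera adjusted p = 1.25e-19), with Atf3 at -8.62 ± 0.56 and Hspa1a, an inducible heat shock chaperone, at -7.75 ± 0.54. Of 23 endothelial genes, 17 fell (median -6.44, camera adjusted p = 2.09e-19), with Fabp4, a fatty acid carrier of capillaries, at -11.49 ± 1.01 and Cdh5 at -9.58 ± 1.56. Of 11 sarcomere genes, 8 fell (median -3.86, camera adjusted p = 1.81e-08). The TGF-beta and BMP list had 9 members lower (median -2.65, camera adjusted p = 1.2e-09), including the receptor genes Bmpr1a (-6.96 ± 0.70) and Bmpr2 (-4.80 ± 0.71). The smooth muscle, calcium handling, Wnt, mesenchymal stem cell, growth factor, cardiac transcription factor, epicardial, chemokine, cardiac stress and Notch lists were lower as well, with medians from -3.66 for smooth muscle to -1.19 for cardiac transcription factors, and each was also called with an estimated correlation. ABC transporters had a median of -0.27 (camera adjusted p = 0.0319, but adjusted p = 0.110 with an estimated correlation).

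With medians aligned only, 928 genes were called (70.5% lower), and 1058 with the deposited values. Without cardiomyocyte replicate 1 or 2 the count was 1221 or 1275.

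MSC had higher cell cycle genes than cardiomyocytes and lower endothelial, muscle and early response genes. Grem1, a secreted BMP antagonist, was 10.29 ± 1.27 higher (SE; limma adjusted p = 0.000389), at 7.45 ± 0.27 (SD, n = 3) against -2.84 ± 0.48 (SD, n = 2). Robo4 was -10.46 ± 1.58 and Pecam1 -8.88 ± 1.25. Tnnt2 fell by 6.99 on the log2 scale, and Pln, the phospholamban gene, was -9.76 ± 1.76.

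For MSC, limma called 1393 genes, 696 higher and 697 lower (50% lower), and 3917 had an unadjusted p under 0.05. Of 23 endothelial genes, 19 fell (median -6.89, camera adjusted p = 1.85e-23), with Cdh5 at -9.84 ± 1.56. Of 11 sarcomere genes, 8 fell (10 when adjusted over the list alone; median -4.67, camera adjusted p = 2.59e-12), with Tnni3 at -6.02 ± 0.60. The calcium handling list fell (median -2.46, camera adjusted p = 6.50e-07), including the calcium store protein gene Casq2 (-5.85 ± 0.96), and so did cardiac transcription factors (median -2.03, camera adjusted p = 4.65e-05; 6 of 18), including Tbx20 (-7.37 ± 1.5) and Gata6 (-5.17 ± 0.76). Immediate early genes fell in 9 of 20 cases (median -2.06, camera adjusted p = 7.97e-11), with Fosb, near the scanner ceiling on 1 of 2 cardiomyocyte arrays, at -5.98 ± 0.76. Notch and smooth muscle genes were lower (medians -2.10 and -2.05, camera adjusted p = 0.000151 and 0.000235). Epicardial genes had a median of -2.20 (camera adjusted p = 0.000151, but adjusted p = 0.0502 with an estimated correlation) and cardiac stress genes one of -1.73 (camera adjusted p = 0.0229, but adjusted p = 0.0592 with an estimated correlation). Of 26 cell cycle genes, 5 rose (9 when adjusted over the list alone; median 2.50, camera adjusted p = 2.19e-06), among them Foxm1, a transcription factor of mitotic genes (5.96 ± 1.43), and the mitotic kinase gene Plk1 (3.94 ± 0.66). Macrophage and leukocyte genes had a median of 2.82 (camera adjusted p = 7.65e-05, but adjusted p = 0.268 with an estimated correlation), and 3 of 20 members rose (8 when adjusted over the list alone). Atp13a3, a P-type transporter gene, was 11.65 ± 1.06 higher, and Mcpt8, a basophil protease gene, 10.80 ± 0.91 higher with 1 of 2 cardiomyocyte arrays at the fill value.

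The share of lower genes was 35.4% of 749 with medians aligned only and 37.0% of 926 with the deposited values. The count was 462 or 855 without cardiomyocyte replicate 1 or 2 and 771, 850 or 801 without MSC replicate 1, 2 or 3. It was 2298 when only the arrays compared were fitted and 2225 with low values raised.

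**Figure D3:**
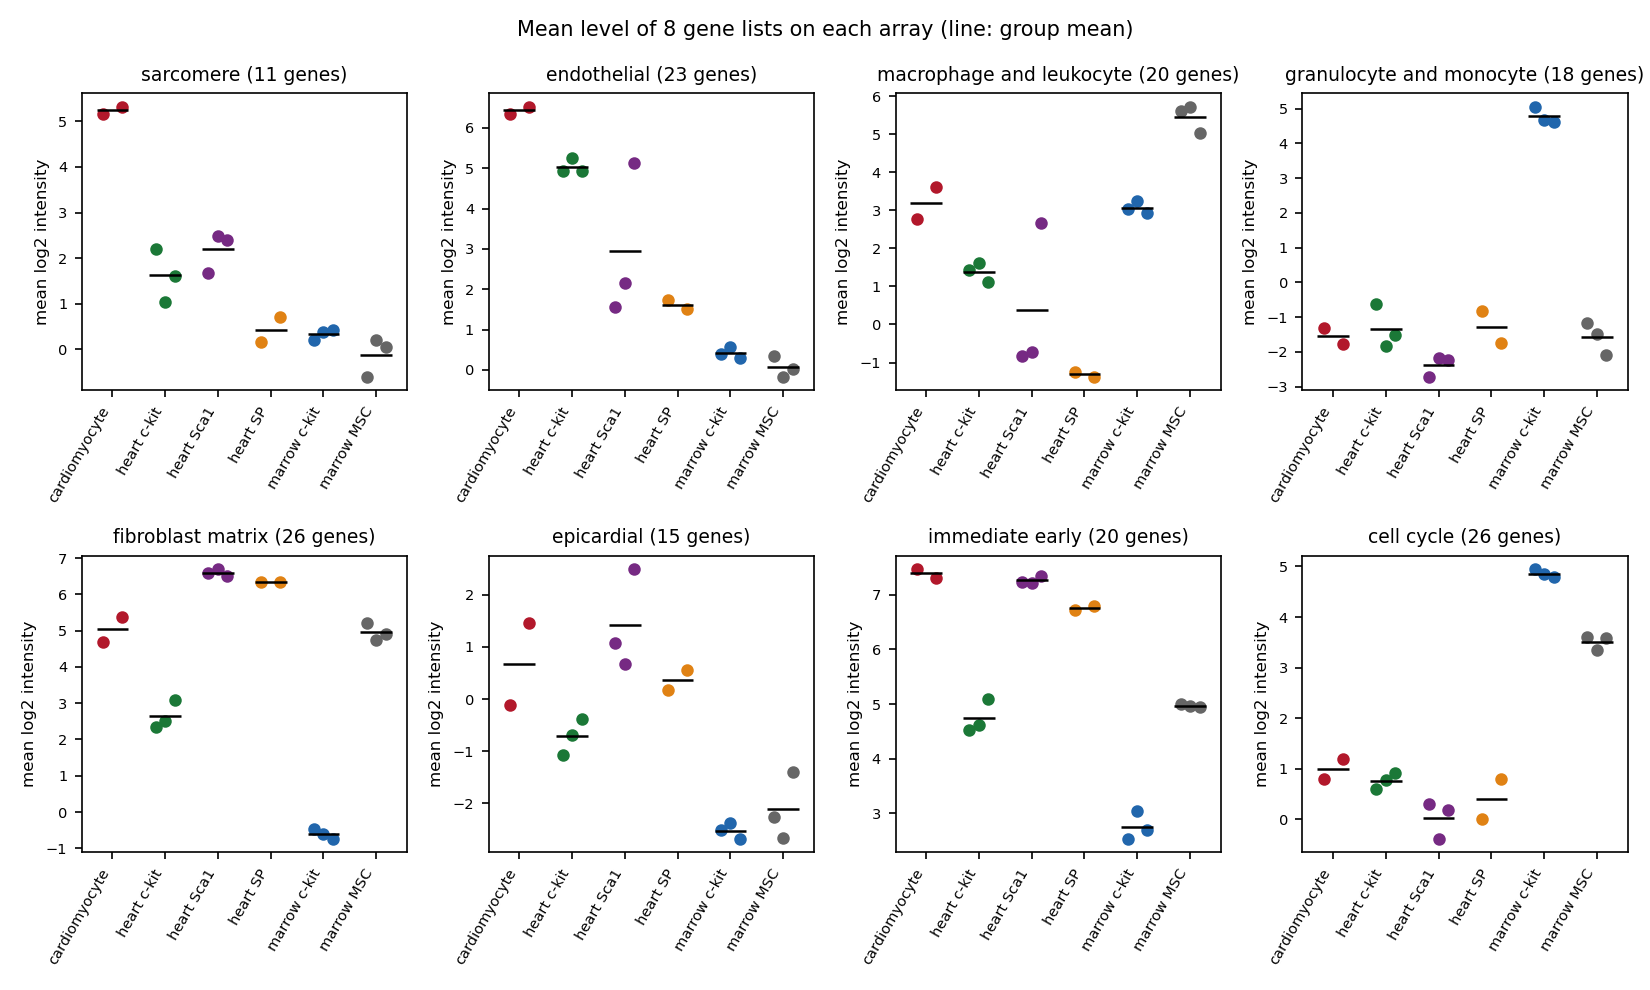
Mean normalised log2 intensity of 8 gene lists (y axes) on each of the 16 arrays by group (x axes); points are arrays and lines group means. Sarcomere genes stand at 5.16 and 5.31 on the cardiomyocyte arrays, macrophage genes at 5.02 to 5.71 on the MSC arrays, and heart Sca1 replicate 3 at 5.14 in the endothelial list against 1.56 and 2.15 in its group.

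The same sort marker was compared between organs in heart and marrow c-kit cells, which the series title relates. Heart c-kit cells had an endothelial, matrix and early response profile, and marrow c-kit cells a granulocyte precursor and proliferating one. Fabp4 was 11.03 ± 0.91 higher in heart c-kit cells (SE; limma adjusted p = 2.89e-06), at 8.61 ± 0.36 against -2.42 ± 2.02 (SD, n = 3 each), and Cxcl1 was 11.85 ± 0.69 higher. S100a9, a calcium-binding protein of neutrophils, was -10.85 ± 0.78 (adjusted p = 1.19e-06) and Mki67, a marker of dividing cells, -8.13 ± 0.95 (adjusted p = 5.46e-05). Kit itself was -1.83 ± 0.87 and did not pass (adjusted p = 0.229).

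Between these groups limma called 1912 genes, 865 higher and 1047 lower in heart c-kit cells (54.8% lower), and 4067 had an unadjusted p under 0.05. Of 18 granulocyte and monocyte genes, 12 fell (16 when adjusted over the list alone; median -7.59, camera adjusted p = 7.39e-16), with the granule protease gene Ctsg at -12.56 ± 0.91 and Prtn3 at -10.99 ± 1.15, each at the fill value on 1 of 3 heart c-kit arrays. Of 26 cell cycle genes, 18 fell and none rose (median -3.76, camera adjusted p = 1.85e-15), with Bub1 at -10.24 ± 0.89 (-4.98 by its other probe, and at the fill value on 1 heart c-kit array) and the mitotic kinase gene Aurka at -6.88 ± 1.95. Of 23 endothelial genes, 16 rose (18 when adjusted over the list alone; median 4.38, camera adjusted p = 1.65e-14), with Cdh5 at 9.39 ± 1.40 and Emcn, an endothelial sialomucin, at 7.38 ± 1.67. Of 26 matrix genes, 12 rose (median 2.60, camera adjusted p = 5.82e-11), with Sparc at 11.44 ± 1.17, Dcn at 7.44 ± 0.77 and the collagen chaperone gene Serpinh1 at 7.17 ± 0.54. Immediate early and heat shock genes rose in 9 of 20 cases (median 1.73, camera adjusted p = 3.56e-07), with Hspa1b at 6.83 ± 0.51 and Dusp1, a kinase phosphatase, at 4.47 ± 0.43. Of 20 TGF-beta and BMP genes, 7 rose (12 when adjusted over the list alone; median 1.90, camera adjusted p = 3.58e-07), with Acvr1 at 3.75 ± 0.61. The Wnt, growth factor, chemokine, Notch, smooth muscle and cardiac stress lists were higher too, with camera adjusted p from 0.00399 to 0.00865, and each was also called with an estimated correlation. The cardiac stress call was lost with the deposited values (adjusted p = 0.0512). Blood stem and progenitor genes had a median of -1.83 (camera adjusted p = 0.00428, but adjusted p = 0.134 with an estimated correlation) and macrophage genes one of -1.56 (camera adjusted p = 0.00493, but adjusted p = 0.337 with an estimated correlation). Epicardial genes had a median of 2.16 and mesenchymal stem cell markers one of 0.60 (camera adjusted p = 0.00865 and 0.00921, but adjusted p = 0.131 and 0.126 with an estimated correlation). Gsta3, a glutathione transferase, and Akr1b8 were 11.27 ± 0.85 and 11.09 ± 0.85 higher, each at the fill value on 1 of 3 marrow c-kit arrays.

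With medians aligned only, 37.6% of 1328 called genes were lower. Without marrow c-kit replicate 2 the count was 1261, and 1067 when only the arrays compared were fitted.

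Heart Sca1 cells and MSC, the stromal pair of heart and marrow, differed in leukocyte and cell cycle genes, which were higher in MSC, and in early response, epicardial and matrix genes, which were higher in heart Sca1 cells. Cx3cr1, the fractalkine receptor of monocytes and macrophages, was -6.98 ± 1.09 (SE; limma adjusted p = 0.000953), at 0.83 ± 3.02 against 7.80 ± 0.51 (SD, n = 3 each). Scara5, a ferritin receptor, was 11.29 ± 0.78 higher (adjusted p = 3.68e-06) and Tek, the angiopoietin receptor gene, 9.01 ± 0.68 higher. Foxm1 fell by 6.44 on the log2 scale.

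Between them limma called 1825 genes, 938 higher and 887 lower in heart Sca1 cells (48.6% lower), and 3912 had an unadjusted p under 0.05. Of 20 macrophage and leukocyte genes, 16 fell (18 when adjusted over the list alone; median -5.36, camera adjusted p = 8.88e-16), with C1qa, of complement, at -8.39 ± 1.79 and the protease gene Ctss at -7.77 ± 1.23. All 3 MSC arrays carried these genes, with mean list levels of 5.61, 5.71 and 5.02. Clec4d, a myeloid lectin receptor, was -11.41 ± 1.00. Of 26 cell cycle genes, 12 fell (median -3.19, camera adjusted p = 1.48e-11), with Aurka at -6.49 ± 1.95. Among 20 immediate early genes, 11 rose and all had positive differences (median 2.00, camera adjusted p = 3.41e-11), with Fosb at 6.05 ± 0.68 (near the scanner ceiling on all 3 heart Sca1 arrays) and Hspa1a at 3.87 ± 0.48. Of 15 epicardial genes, 7 rose (median 2.38, camera adjusted p = 1.32e-06), with the retinaldehyde dehydrogenase gene Aldh1a1 at 8.99 ± 1.26 and the transcription factor genes Tcf21 and Wt1 at 9.0 ± 1.56 and 7.11 ± 1.10, each at the fill value on 1 MSC array. Of 26 matrix genes, 9 rose and 1 fell (median 1.65, camera adjusted p = 2.46e-05), with Col3a1 at 6.36 ± 0.68 and Pcolce, a collagen-processing enhancer, at 3.45 ± 0.60. Of 18 cardiac transcription factors, 6 rose (median 1.34, camera adjusted p = 0.00122). Of 11 sarcomere genes, 5 rose (median 2.07, camera adjusted p = 0.000886), and Wnt genes had a median of 0.81 (camera adjusted p = 0.00497). Endothelial genes had a median of 2.28 (camera adjusted p = 8.94e-08, but adjusted p = 0.159 with an estimated correlation), with Ramp2 at 7.48 ± 0.58, and the endothelial level of heart Sca1 replicate 3 was 5.14 against 1.56 and 2.15 for the other arrays of its group. The TGF-beta list had a median of 0.66 (camera adjusted p = 0.0150, but adjusted p = 0.255 with an estimated correlation).

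The count was 1160 without MSC replicate 1, 1146 without MSC replicate 2 and 1208 without heart Sca1 replicate 2. It was 3860 when only the arrays compared were fitted and 4259 with array weights.

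The effects of organ in the c-kit pair and in the stromal pair were also compared directly, by an interaction of organ and cell class that was added after the planned comparisons. In the stromal pair MSC were passaged and heart Sca1 cells sorted, but the growth label names the same culture medium for every sample, so it is unclear whether the sorted cells were cultured too. limma called 1315 genes whose heart minus marrow difference was not the same in both pairs, 646 with a more positive difference between c-kit cells and 669 with a more positive one between stromal cells.

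Within the heart, c-kit cells were set against Sca1 cells. Heart c-kit cells had lower matrix and early response genes and higher Kit. Col6a1 was -6.35 ± 0.55 (SE; limma adjusted p = 1.17e-05), at 0.62 ± 0.62 against 6.96 ± 0.27 (SD, n = 3 each), and Dkk3, a secreted Wnt modulator, was -10.33 ± 0.74 (adjusted p = 2.14e-06). Cma1, mast cell chymase, was 5.43 ± 0.74 higher and Tpsb2, a mast cell tryptase, 4.2 ± 0.74 higher.

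In all, limma called 1966 genes, 582 higher and 1384 lower in heart c-kit cells (70.4% lower), and 4862 had an unadjusted p under 0.05. Of 26 matrix genes, 18 fell and none rose (20 lower when adjusted over the list alone; median -4.31, camera adjusted p = 3.51e-16), with Col1a2 at -6.55 ± 0.96. Of 20 immediate early genes, 12 fell (median -2.09, camera adjusted p = 2.56e-08), with Fosb at -6.89 ± 0.68 and Nr4a1, an orphan nuclear receptor, at -4.49 ± 0.52, near the scanner ceiling on 3 and 2 of 3 heart Sca1 arrays. The other lists called by camera lost their call with an estimated correlation. Endothelial genes had a median of 2.66 and 7 rose (camera adjusted p = 0.00280, but adjusted p = 0.305 with an estimated correlation), with Sox18 at 5.01 ± 0.97 and Cdh5 at 5.24 ± 1.40. Heart Sca1 replicate 3 again carried more of this list than its group, 5.14 against 1.56 and 2.15. Of 15 epicardial genes, 4 fell (median -1.98, camera adjusted p = 0.0142, but adjusted p = 0.187 with an estimated correlation), with Efemp1 at -5.77 ± 0.80. Of 27 Wnt genes, 7 fell (median -1.30, camera adjusted p = 0.0274, but adjusted p = 0.110 with an estimated correlation), with the secreted Wnt inhibitor gene Sfrp1 at -5.73 ± 1.01. Of 14 mast cell genes, 4 rose, namely Cma1, Kit, Tpsb2 and Cpa3 (3.09 ± 0.89, with overlapping arrays), and the median was 1.28 (camera adjusted p = 0.0274, but adjusted p = 0.110 with an estimated correlation). Fatty acid oxidation genes had a median of -0.88 (camera adjusted p = 0.0274, but adjusted p = 0.110 with an estimated correlation). The TGF-beta (median -0.49), smooth muscle (median -1.06) and cardiac transcription factor lists (median -0.73) were lower, with camera adjusted p of 0.0285, 0.0425 and 0.0425 but adjusted p = 0.200, 0.187 and 0.184 with an estimated correlation. The macrophage (median 0.96), granulocyte (median 0.92) and erythroid lists (median 1.36) were higher, each with a camera adjusted p of 0.0425 but adjusted p = 0.469, 0.200 and 0.200 with an estimated correlation. Slpi, a secreted protease inhibitor, was 7.12 ± 0.90 higher, and Scn7a, a sodium channel gene at the fill value on 1 of 3 heart c-kit arrays, was -10.96 ± 1.08.

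With the deposited values, 82.4% of 1554 called genes were lower. The count was 1189 or 1248 without heart Sca1 replicate 1 or 2 and 780 when only the arrays compared were fitted.

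Side population cells were compared with both sorted heart populations. Against side population cells, heart c-kit cells had lower matrix and early response genes. Laptm5 was 9.07 ± 0.79 higher (SE; limma adjusted p = 1.18e-05) and Cdh5 8.61 ± 1.56 higher (adjusted p = 0.00261). Dkk3 was -11.12 ± 0.83, at -3.52 ± 0.64 (SD, n = 3) against 7.60 ± 0.01 (SD, n = 2), and Fosb was -6.97 ± 0.76, near the scanner ceiling on both side population arrays.

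Between these populations limma called 2087 genes, 1061 higher and 1026 lower in heart c-kit cells (49.2% lower), and 4560 had an unadjusted p under 0.05. Of 26 matrix genes, 17 fell and 1 rose (median -4.07, camera adjusted p = 1.96e-13), with Col1a2 at -6.27 ± 1.07 and Postn, the matricellular protein periostin, at -6.39 ± 1.57. Immediate early genes fell in 7 of 20 cases (median -1.45, camera adjusted p = 6.51e-05), with Nr4a1 at -3.93 ± 0.58. Of 23 endothelial genes, 13 rose and 1 fell (median 3.92, camera adjusted p = 1.43e-06, but adjusted p = 0.201 with an estimated correlation), with Robo4 at 6.97 ± 1.58 and Emcn at 6.6 ± 1.87. Of 20 macrophage genes, 6 rose (median 1.53, camera adjusted p = 0.000176, but adjusted p = 0.278 with an estimated correlation). Of 18 cardiac transcription factors, 4 fell (median -0.95, camera adjusted p = 0.0222, but adjusted p = 0.141 with an estimated correlation), with Hand2 at -7.45 ± 1.25 and Mef2c at -3.42 ± 0.64. The Notch list (median 1.03) and the growth factor list (median -0.66) each had a camera adjusted p of 0.0455 but adjusted p = 0.153 and 0.201 with an estimated correlation. Dll4, an endothelial Notch ligand, was 3.94 ± 0.89 higher. Pdgfrl was -10.64 ± 1.08.

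Between heart Sca1 and side population cells single genes passed, but no gene list did. Tnni3 was 5.43 ± 0.60 higher (SE; limma adjusted p = 0.000208), at 5.32 ± 0.59 (SD, n = 3) against -0.11 ± 0.34 (SD, n = 2). Gpd1, a glycerol phosphate dehydrogenase near the scanner ceiling on 1 of 2 side population arrays, was -9.79 ± 1.68 (adjusted p = 0.00461), and Csf2 was -7.93 ± 1.25. Here limma called 1210 genes, 819 higher and 391 lower in heart Sca1 cells (32.3% lower), and 4108 had an unadjusted p under 0.05. Ro60, an RNA-binding autoantigen, was 9.49 ± 1.04 higher, Lrch1 9.28 ± 1.04 higher and Laptm5 6.30 ± 0.79 higher. Epb41l4a was -7.28 ± 1.26. Among the lists, the smallest camera adjusted p was 0.0637 for erythroid, granulocyte and endothelial genes alike. Of 11 sarcomere genes, 3 rose (median 0.67, camera adjusted p = 0.113), and Xirp1, of the cardiac stress list, was -3.57 ± 0.73.

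Both comparisons depended on scaling and on the arrays in the fit. With medians aligned only, 69.9% of 1716 called genes were lower in heart c-kit cells and 72.3% of 1707 were lower in heart Sca1 cells, against 16.8% of 1043 in the latter with the deposited values. When only the arrays compared were fitted the counts were 77 and 176, with array weights 492 and 336, and without heart Sca1 replicate 1, 2 or 3 the second was 645, 660 or 556.

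**Figure D4:**
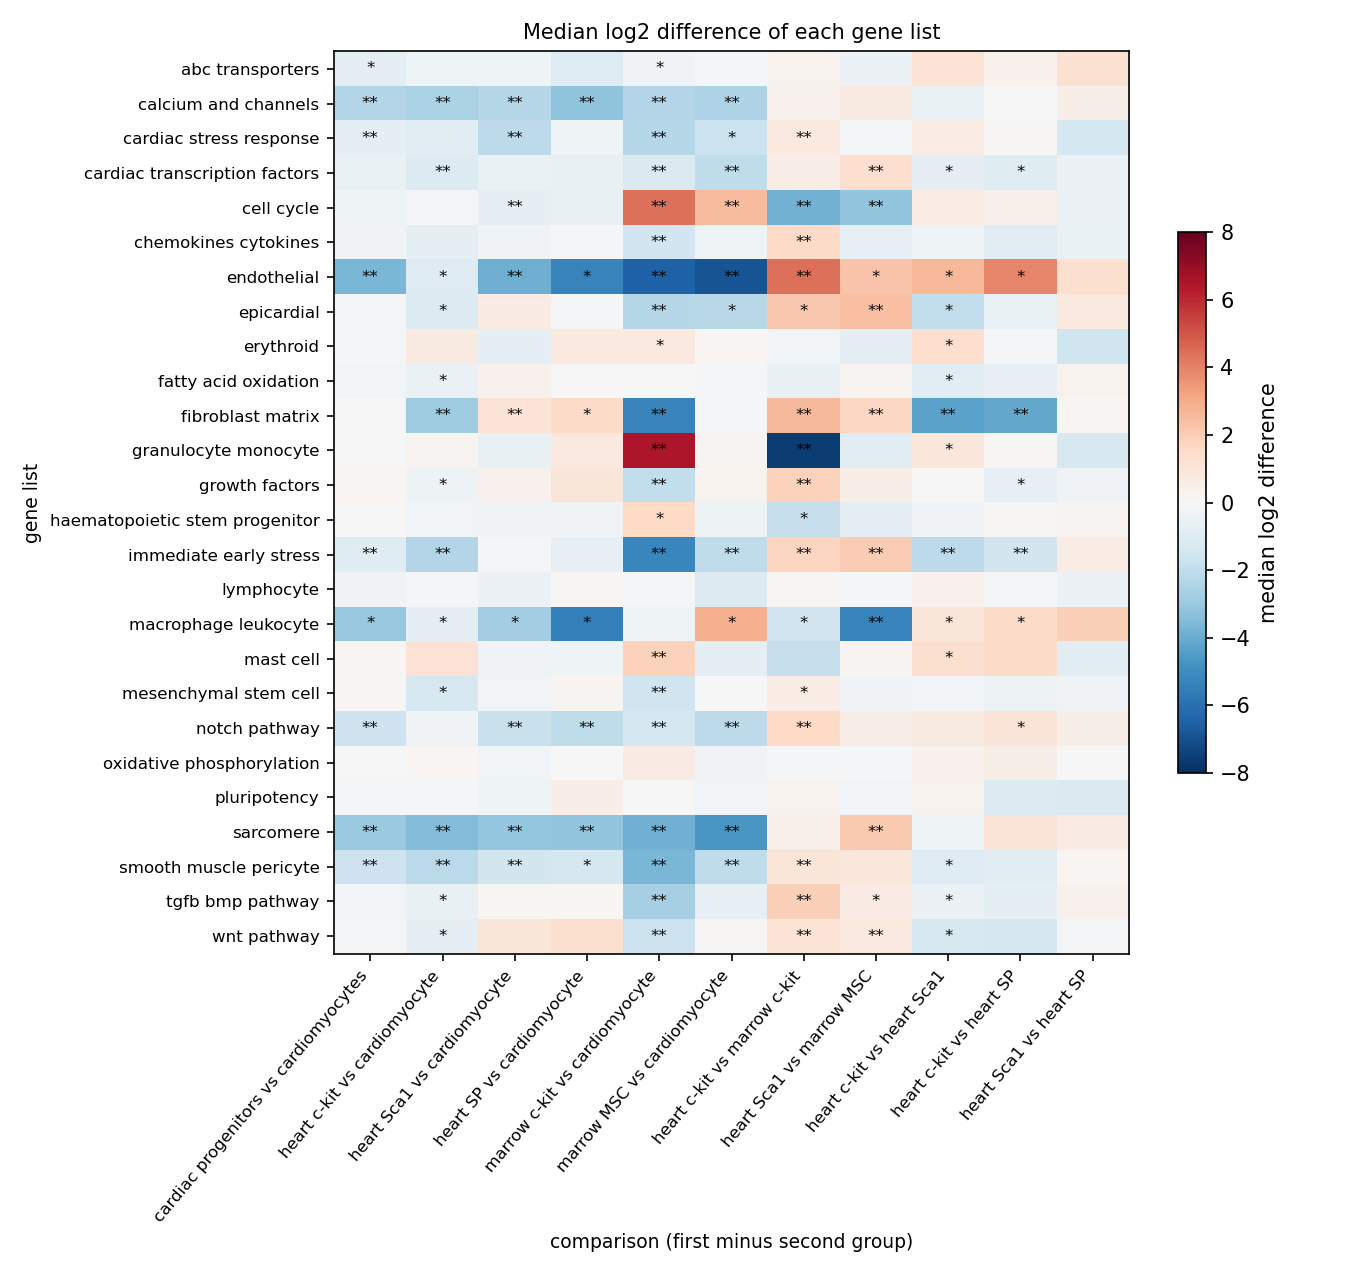
Median log2 difference (colour) of each of the 26 gene lists (y axis) in the 11 comparisons (x axis), first minus second group; 1 star marks a camera call with the preset correlation only and 2 stars a call that also held with an estimated correlation. The most negative cell is granulocyte and monocyte genes in heart against marrow c-kit cells (-7.59) and the most positive the same list in marrow c-kit cells against cardiomyocytes (6.45).

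Over the 286 pairs of list and comparison, camera called 117 with its preset correlation and 74 of them with an estimated one. Lymphocyte, pluripotency and oxidative phosphorylation genes were called in no comparison, with smallest adjusted p of 0.315, 0.647 and 0.107. With another scaling the median log2 difference of all genes moved, from a range of -0.10 to 0.23 over the comparisons to -1.29 to 1.34 with medians aligned only and -0.23 to 0.31 with the deposited values. Of the 117 calls, 16 were lost with medians aligned only and 18 with the deposited values. Of the 117 called list medians, 9 changed sign with medians aligned only and 4 with the deposited values. Measured relative to the median of all genes, 3 did so under each scaling, namely immediate early genes and ABC transporters in cardiac progenitors and endothelial genes in heart c-kit cells, all against cardiomyocytes.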

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

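The tests of these patterns were chosen after the results were seen. The interaction of organ and cell class gave the largest departure: granulocyte and monocyte genes had a median heart minus marrow difference of -7.59 between c-kit cells and -0.87 between stromal cells, where the list was not called (camera adjusted p = 0.139). The interaction median was -6.93 (limma camera adjusted p = 4.63e-09, and 0.0202 with an estimated correlation). Of the 18 genes in the list, 1 is shared with another list. The mean level of the list was 4.78 in marrow c-kit cells and between -2.38 and -1.29 in every other group. The interaction thus came from the high level in marrow c-kit cells. No further explanation was tested for it. In the stromal pair MSC were passaged, while the growth label leaves unclear whether sorted cells were cultured. Macrophage genes (3.41, camera adjusted p = 7.34e-06), chemokines (1.69, 0.0190) and mesenchymal stem cell markers (1.45, 0.0260) differed only with the preset correlation; with an estimated one the adjusted p was 0.331, 0.239 and 0.331.

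For the markers of other cells on the cardiomyocyte arrays, the tests were chosen after the levels had been seen. The median member of the endothelial, macrophage and fibroblast lists lay at or above percentile 80.6 of all genes on these arrays, which restates the pattern and ranks different probes against each other, so it decides nothing. The endothelial median of cardiac progenitors minus cardiomyocytes stayed at -1.91 or further from 0 under 3 scalings. That argues against scaling for the mean of the 3 cardiac populations. It does not for heart c-kit cells alone. Their median of -1.03 turned to 0.89 with medians aligned only and 0.19 with the deposited values (camera adjusted p = 0.463 and 0.562). These last scalings differ only by a shift of each array, so they are not separate checks. The percentiles within the cardiomyocyte arrays would not move with such a shift. Of 23 endothelial genes 2 are shared with another list, of 20 macrophage genes 0. Whether other heart cells were present in a preparation made by slow centrifugation without a sort gate stays open, and a purified myocyte sample would test it.

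Heart Sca1 replicate 3 was picked after the levels per array had been seen, in place of a resemblance of heart c-kit replicate 1 to a cardiomyocyte array, and its tests were chosen then. Its endothelial and macrophage lists exceeded the mean of the other arrays of the group by 3.28 and 3.43, although the gate excluded CD31 and CD45; Pecam1 stood at 5.38 against 1.57 and 3.39, and Ptprc at 2.94 against 0.40 and -0.89. Other lists rose less on that array, among them epicardial (1.62), Notch (1.49), blood stem and progenitor (1.37), mast cell (1.27), chemokine (1.15) and smooth muscle genes (0.99). The sarcomere excess was 0.32, which argues against cardiomyocyte RNA as the source of the endothelial and macrophage excess. It does not exclude muscle RNA common to the 3 arrays of the group, where Tnni3 stood at 4.64, 5.67 and 5.66. Relative to the mean of all genes on each array, the endothelial excess was 3.24 after quantile normalisation and 3.27 in the deposited values. A shift of the whole array would leave no such excess, and quantile normalisation did not create it. Alignment of medians shifts whole arrays only, so it had to give the same 3.27 and adds nothing. Endothelial and blood cells within that sorted sample stay open, since the excess itself is the pattern and no other value decides it.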

How the results depend on the processing

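Alignment of medians and centring each array on its own median coincide, and they were run once. It gave 0 genes for cardiac progenitors against cardiomyocytes, 148 for heart c-kit cells, 2619 for side population cells, 928 for marrow c-kit cells and 749 for MSC, each against cardiomyocytes, and a distance gap of 0.962 with a permutation p of 0.0549. The median of immediate early genes in cardiac progenitors turned to 1.23, and to 0.50 with the deposited values. Removal of the lowest 30% of genes gave 228 genes for cardiac progenitors, trend and robust moderation 196, and the mean over probes 2 for heart Sca1 cells against cardiomyocytes. With an estimated correlation 74 gene lists were called in place of 117.

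When only the arrays compared were fitted, the counts against cardiomyocytes were 0 for cardiac progenitors, 3 for heart c-kit cells, 0 for side population cells and 2298 for MSC. They were 1067 for heart against marrow c-kit cells, 3860 for heart Sca1 cells against MSC, 780 for heart c-kit against Sca1 cells, and 77 and 176 for heart c-kit and Sca1 cells against side population cells.

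Replicate numbers showed no pairing of samples across all groups. Residuals of 36 pairs of arrays with the same number had a mean correlation of 0.0231 (highest 0.399), with 4 above 0.1. For 70 pairs with different numbers the mean was -0.0119 (highest 0.324). Residuals cancel out within a group, so the second mean largely follows from the first. A batch in some groups is not excluded. Replicate 1 of marrow c-kit cells, heart c-kit cells and cardiomyocytes had deposited SDs of 3.29, 2.90 and 2.95. Other arrays of these groups had 3.43 to 4.03. A block for replicate number gave 38 genes for cardiac progenitors.

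A few alternatives were chosen after the data had been seen. The deposited values gave 2 genes for cardiac progenitors, 223 for heart c-kit cells, 1058 for marrow c-kit cells and 926 for MSC, all against cardiomyocytes. Raising values to the 30th percentile gave 505, 1115, 325, 1486 and 2225 for cardiac progenitors, heart c-kit, heart Sca1, side population cells and MSC against cardiomyocytes. Array weights per group gave 4, 242 and 128 for cardiac progenitors, heart c-kit cells and side population cells against cardiomyocytes, 4259 for heart Sca1 cells against MSC, and 492 and 336 for heart c-kit and Sca1 cells against side population cells. The weights were 2.18 for MSC, 0.470 for heart c-kit and 0.393 for side population arrays, where the main fit treats all arrays alike. Counts with array weights differ from the main fit through these weights alone. The cause was not tested for the other shifts.

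Leaving out an array at a time gave 1 to 240 genes for cardiac progenitors, 180 to 941 for heart c-kit cells, 0 to 164 for heart Sca1 cells, 260 to 1274 for side population cells, 1221 to 1727 for marrow c-kit cells and 462 to 855 for MSC against cardiomyocytes. The range was 1261 to 2163 for heart against marrow c-kit cells, 1146 to 1375 for heart Sca1 cells against MSC and 1189 to 2537 for heart c-kit against Sca1 cells. Against side population cells it was 2065 to 2255 for heart c-kit cells and 556 to 1412 for heart Sca1 cells, and the distance gap was 0.427 to 0.980. The cause was not tested. Dim arrays, with median intensities of 15, 22 and 18, limit what can be read for weak genes.

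Over the alternatives, results of named genes stayed the same in 4183 cases, became weaker in 548 and stronger in 15. Results of the 6 top lists of each comparison stayed the same in 429, weaker in 22, stronger in 9 and reversed in 2. Both tallies cover genes and lists picked mostly for strong differences. Of all 117 list calls, 74 held with an estimated correlation, 16 were lost with medians aligned only and 18 with the deposited values.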

Other observations

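The overlap of the heart and marrow differences was chosen for a test after the comparisons were planned and before its result was seen. Part of the heart minus marrow difference was shared by c-kit and stromal cells, which have no array in common. Both pairs were normalised together and use the same estimate of the spread of each gene, however. A gene with a small spread is called more easily in both, so independent calls are not an exact reference. In the stromal pair MSC were grown for 5 passages and heart Sca1 cells were sorted, but the growth label is the same for every sample, so it is unclear whether organ coincides with culture. Genes called higher in heart in both pairs numbered 178 where independent calls would give 45.8, a ratio of 3.89, and genes called lower in both numbered 243 where 52.4 would be given. Calls in opposite directions numbered 43 and 56, where 43.3 and 55.5 would be given, and the log2 differences of the pairs correlated over genes with r = 0.227. Shared higher genes included the endothelial genes Tek (6.31 and 9.01), Sox7 (8.61 and 7.63) and Fgd5 (6.79 and 9.33), the mesothelial factor Wt1 (8.74 and 7.11) and the muscle gene Unc45b (7.0 and 5.92). Shared lower genes included Ccna2 (-8.73 and -8.23) of dividing cells and Was (-8.34 and -7.11) and Runx3 (-7.50 and -8.69) of blood cells. All of these but Tek and Was were at the fill value on 1 or more arrays of the lower side, so their sizes are uncertain. A common organ signature may explain the overlap. For the shared higher genes, muscle and endothelial cells carried along in the sorted heart samples could as well, although the heart Sca1 gate excluded CD31 and CD45. For the shared lower genes, lists of dividing and blood cells were high in both marrow groups. The cell cycle list stood at 4.86 in marrow c-kit cells and 3.51 in MSC, against 0.77 in heart c-kit and 0.03 in heart Sca1 cells. The macrophage list stood at 3.06 and 5.45 against 1.39 and 0.37. Which of these explains the overlap was not tested.

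Genes of the oxidative stress response in heart c-kit cells were tested after genes such as Akr1b8 and Gsta3 had been seen among the highest. A new list of 26 genes without those, of which 23 were measured, had medians of 1.73 against heart Sca1 cells, 1.79 against cardiomyocytes, 1.05 against side population cells and 1.32 against marrow c-kit cells. The highest limma camera adjusted p with an estimated correlation over these comparisons was 0.0131. Against heart Sca1 cells, Gclc and Gclm of glutathione synthesis were 4.90 and 5.17 higher and Gsr 3.66 higher. The list mean was 4.44, 4.44 and 4.49 on the heart c-kit arrays and at most 3.62 elsewhere. With medians aligned only the camera p, not adjusted, was 0.164 against heart Sca1 cells, 0.0359 against cardiomyocytes, 0.536 against side population cells and 0.0631 against marrow c-kit cells. With the deposited values these were 0.0569, 0.00659, 0.391 and 0.0143. The medians against heart Sca1 cells, cardiomyocytes and marrow c-kit cells were 2.14, 3.07 and 2.41 with medians aligned only, where those of all genes were 0.73, 0.83 and 0.77. They were 1.65, 2.37 and 1.75 with the deposited values, where those of all genes were 0.23, 0.13 and 0.10. Against side population cells the median was -0.33 where that of all genes was -0.58, and 0.23 with the deposited values, so there the list still lay above all genes, but by less. The pattern is not settled, since most calls were lost; this requirement was added after the first result. The 4 comparisons share the heart c-kit arrays. The signal may reflect the state of the cells in the heart or a response to isolation, and a sort of the same cells with and without antioxidants could separate these.

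Leukocyte genes on the MSC arrays were examined with tests chosen after they had been seen. All 3 MSC arrays lay above all 10 arrays of heart cells in the macrophage and leukocyte list (lowest MSC level 5.02, highest heart level 3.62), while 0 did so in the lymphocyte list. Granulocyte genes were only 0.87 higher in MSC than in heart Sca1 cells, which argues against RNA of marrow c-kit cells. The macrophage difference was 5.36 or larger under 3 scalings, which argues against scaling. Medians aligned only and the deposited values differ just by a shift of each array, so they are not separate checks. Macrophages that persisted through 5 passages stay open, since the height of these genes is the pattern itself, and a stain for CD45 and CD11b on cells of that passage would test it.

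Regrouping of arrays was chosen as a test before its result was seen. For heart against marrow c-kit cells, heart Sca1 cells against MSC, and heart c-kit against Sca1 cells, the real grouping gave 1912, 1825 and 1966 genes, and the highest other of the 10 splits of the 6 arrays gave 1, 0 and 1. Only 1 of 10 splits gave as many in each case, and 10 splits are too few for a share under 0.05. Every other split also puts arrays of both groups on each side, which raises the spread and shrinks the difference. Low counts were bound to follow, so they do not show what chance alone would give.

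Heart c-kit replicate 1 correlated more with cardiomyocyte replicate 1 (r = 0.874) than with its own group (at most 0.805). In the brighter part of the genes, 8855 of them, the values were 0.712 against 0.610 and 0.623. Its sarcomere level was 2.21 against 1.04 and 1.60 on the other arrays of the group. Heart Sca1 replicate 3 correlated most with cardiomyocyte replicate 2 (r = 0.933, against at most 0.917 in its own group), and cardiomyocyte replicate 2 most with it (0.894 with the other cardiomyocyte array). In the brighter genes these values were 0.900 for the heart Sca1 array and 0.735 for the cardiomyocyte pair. Heart c-kit replicate 3 also matched cardiomyocyte replicate 2 best (0.820), and both side population arrays matched heart Sca1 replicate 2 best (0.765 and 0.776, against 0.748 with each other). The sarcomere levels of 2.21 on heart c-kit replicate 1 and 2.40 on heart Sca1 replicate 3 stood well below the 5.16 and 5.31 of the cardiomyocyte arrays. The sarcomere excess of 0.32 on heart Sca1 replicate 3 argues against more cardiomyocyte RNA there than on the other arrays of its group. For the other matches neither mixing of samples nor a shared batch was tested. Heart c-kit replicate 1 and cardiomyocyte replicate 1 had the lowest SDs of deposited values, 2.90 and 2.95.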
